A study of Mus musculus with 49 samples.

How the data were processed

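The data are 1 table of expression values for 49 individual cells from microdissected metanephric mesenchyme of Crym-EGFP mouse embryos at 11.5 days post coitum. Per the labels' protocols, the tissue was dissociated with trypsin, cells were captured on a microfluidic chip (Fluidigm C1) whose chambers were inspected under a microscope, complementary DNA was made and amplified with the SMARTer chemistry, and libraries were made with transposase (Nextera XT) and sequenced on a HiSeq2500. This chemistry keeps no strand information and no molecular identifiers, so a value reflects amplified molecules, and reads from overlapping genes on opposite strands are not told apart.

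The deposited values are RPKM, reads scaled to the length of the gene and to the mapped reads of the cell, computed by the authors per the file headers. TopHat 1.4.1, DESeq and the mouse genome build mm9 are named in the submitters' processing notes, which give no role or order. The read counter and the annotation are not given in the sources used here. The 13093 genes of the table are those with more than 3 RPKM in at least 1 cell: this was checked on the values, and the deposited count of cells above 3 RPKM matched in all 13093 genes. A gene that was low in every cell is therefore outside the analysis, and list members outside the table are described as not analysed here. Coordinates are given as in the table, and whether its starts count from 0 or 1 is not given in the sources used here. Rows were kept apart by gene ID, since 26 symbols stood on more than 1 row; none belonged to a gene list. No column of values per cell was left unused (0 columns).

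Cells were matched to columns by the cell number in both names. All cells form 1 group, and since no embryo or litter is named the group counts as 1 sample: shares of cells are given with an exact (Clopper-Pearson) 95% binomial interval that covers counting error only, a share of 0 with the limit that 3 cells of the total allow, and no p-values were computed. No doublet caller was run on so few cells; the microscope record of the chambers is the submitters' treatment of doublets, and 2 cells with genes of another cell type were kept and also left out as an alternative. No cell was filtered. A gene counted as detected at 1 RPKM or more. Pairs of genes were compared by the number of cells that detected both, beside the number expected if detection were independent (the product of both counts divided by 49).

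Total reads per cell are not in the table, and the sums of RPKM per cell, 396959 to 526418, do not give depth. Relative depth was estimated from the steps between low values. For genes below 8 RPKM in a cell and in cell 1, the ratio of the 2 values piles up where both cells hold equal small numbers of reads, and the densest window of 2e-05 in the natural log of the ratio was taken; it held at least 63 of at least 883 genes in every cell. Only the relative depth is used, and reads per gene were not recovered. A cell with fewer reads, such as cell 3 or cell 7, has coarser values.

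Gene lists were fixed before the data were examined: nephron progenitor, stroma, ureteric bud, endothelial, macrophage, erythroid, neural, muscle, early nephron, podocyte, proximal tubule, loop and distal tubule, signalling, G1/S, G2/M, housekeeping, dissociation stress, Y-linked genes and Xist. List coherence is the median Spearman correlation over pairs of list genes detected in 5 or more cells, set against 10000 random lists of the same size drawn from 20 bins of mean log2(RPKM+1); it was computed for lists with at least 4 such genes, and the correlation between the nephron progenitor and stroma lists was set against 10000 pairs of matched lists. Clusters were made by Ward linkage on the first 5 principal components of log2(RPKM+1), a pseudocount of 1, for the 500 genes with the largest SD residual on the mean among those detected in 5 to 44 cells; the number from 2 to 6 with the highest mean silhouette was taken. Differences on this scale understate the change of low genes.

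Genes were named by a rule set before the data were examined: members of the fixed lists, with the main lists in full and 2 to 4 of the members detected in most cells for others (more for signalling genes); Hox genes, up to 10 of those detected in most cells; the 15 genes with the largest SD residual among those detected in 20 to 80% of cells; up to 10 genes that define a cluster; and the 10 genes with the highest mean. Further names (Abca14, Tmem159, Tpm4, Taldo1, Enc1, Kpna2, Rrm2, Tubb4b, and list members singled out for the value of 1 cell) were chosen after the values were seen. Contrary to the rule on main lists, and after the results were seen, some list members that were analysed with their list were left out of the text and figures; they are not reported here by name.

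The estimate of relative depth, list coherence and the number of clusters were first tested on simulated data; counts of cells and the comparisons with an even trace of the lane were not. Relative depth was recovered within 1% in all 49 simulated cells, on 13093 genes. The simulated values were whole reads over a fixed length per gene, so departures from whole reads in the real values were not covered. A planted list of correlated genes lay at percentile 100 among random lists, and 5.5% of 200 unplanted lists lay above the 95th percentile, on 10246 genes. For 3 planted groups of cells, 3 clusters were found, with an adjusted Rand index of 0.883, on 500 genes. Alternatives set before the data were examined were detection thresholds of 0.1, 5 and 10 RPKM, Pearson correlation with pseudocounts of 1 and 0.1, removal of the trend with genes detected per cell, other filters, pseudocounts, numbers of variable genes and of components, and leaving out cells with few genes; leaving out cells 3 and 7, cells 25 and 27, or the list genes detected in 40 or more cells was chosen after seeing the data. The software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.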

Results

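RNA was sequenced from 49 individual cells of the mouse metanephric mesenchyme at 11.5 days post coitum (Theiler stage 19), the tissue around the ureteric bud from which nephrons and kidney stroma arise. The embryos carried a Crym-EGFP transgene, and the dissection followed its fluorescence and took some cells beyond the edge of the labelled domain. The labels name no embryo or litter, so the 49 cells form 1 group that counts as 1 sample. Cells were not treated as replicates and no p-values were computed. A median of 5210 genes per cell reached 1 RPKM, from 3610 in cell 44 to 6510 in cell 47, out of 13093 genes analysed. The highest mean levels were those of Eef1a1 at a mean of 6455 RPKM, Actb at 4681, Ppia at 3235, Actg1 at 3194, Rpl41 at 2854, Rps14 at 2685, H2afz at 2333, Ptma at 2251, Gm1821 at 2219 and Rps3a at 2048. Ribosomal protein genes have many processed copies in the genome, so their values are uncertain. The means of Rps14 and Rps3a were also raised by cell 3, a library with few reads, where they stood at 24008 and 18482 RPKM. Their medians over all cells were 2199 and 1695 RPKM, the latter below those of Rplp0 at 1916 and Ubb at 2009. The relative number of reads, taken from the steps between low RPKM values, lay between 0.693 and 1.52 times that of the median cell in 47 cells. It was 0.0346 in cell 3 and 0.0462 in cell 7. In these 2 shallow libraries single genes reached the highest values of the data set, with Tpm4 at 42533 RPKM in cell 3 and Taldo1 at 27238 RPKM in cell 7.

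**Figure D1:**
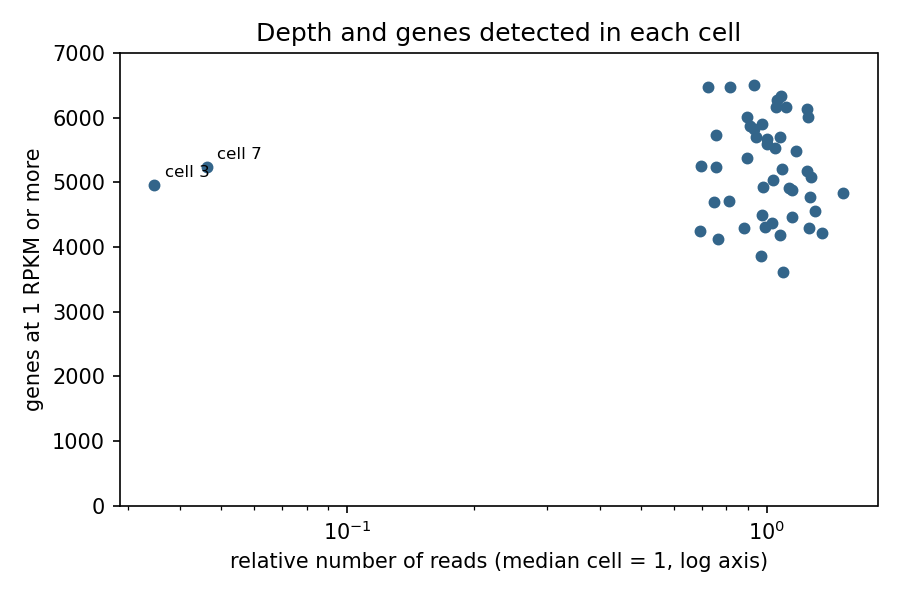
Genes at 1 RPKM or more in each of the 49 cells (vertical axis) against the relative number of reads of the cell (horizontal log axis, median cell set to 1). Each point is 1 cell; cells 3 and 7 lie at 0.0346 and 0.0462, and the other 47 cells between 0.693 and 1.52.

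Crym, which encodes the thyroid hormone binding protein mu-crystallin and drives the reporter, was compared with Six2, the transcription factor that maintains nephron progenitors, because the labels describe their domains at this stage as equal. Crym (gene ID 12971; chromosome 7, 127329898 to 127345502 in mm9) was at 1 RPKM or more in 48 of 49 cells (98.0%, exact 95% binomial interval 89.1 to 99.9%). Its values fell into 2 ranges: 30 cells had 31.4 to 1480 RPKM, and 19 cells had 0.999 to 4.92 RPKM, with no cell at 0 and none in between. Six2 (gene ID 20472; chromosome 17, 86083608 to 86087594) was at 1 RPKM or more in 27 cells (55.1%, interval 40.2 to 69.3%), with a median of 46.1 RPKM in those cells and a highest value of 117 RPKM in cell 15. At the threshold of 1 RPKM, Crym and Six2 were detected together in 27 cells, where independent detection would give 26.4; nearly every cell passed this threshold for Crym. At 10 RPKM, 30 cells had Crym, 19 had Six2 and 18 had both, against 11.6 for independent detection.

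Of the 30 cells in the high range of Crym, 24 had Six2 at 1 RPKM or more. In the remaining 6 cells of that range Six2 was listed at 0 (cells 7, 32, 38, 41 and 42) or at 0.471 RPKM (cell 44). Eya1, a transcriptional coactivator needed for metanephric induction, stood at 281 RPKM in cell 32, 106 RPKM in cell 44, 98.6 RPKM in cell 38, 72.4 RPKM in cell 41 and 20.0 RPKM in cell 7, and at 0.467 RPKM in cell 42. Foxd1, a stromal transcription factor, stood at 42.9 RPKM in cell 41 and 14.3 RPKM in cell 7, beside Eya1 in both, and at 10.0 RPKM in cell 42. Of the 19 cells in the low range of Crym, 3 had Six2, at 25.9 RPKM in cell 8, 5.94 RPKM in cell 6 and 3.73 RPKM in cell 31. The values are RPKM computed by the authors, and a 0 in a single cell can be a transcript that was missed: the housekeeping genes Tbp and Hprt were listed at 0 in 19 and 6 cells. Intervals on shares of cells cover counting error only, not the spread between embryos.

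**Figure D2:**
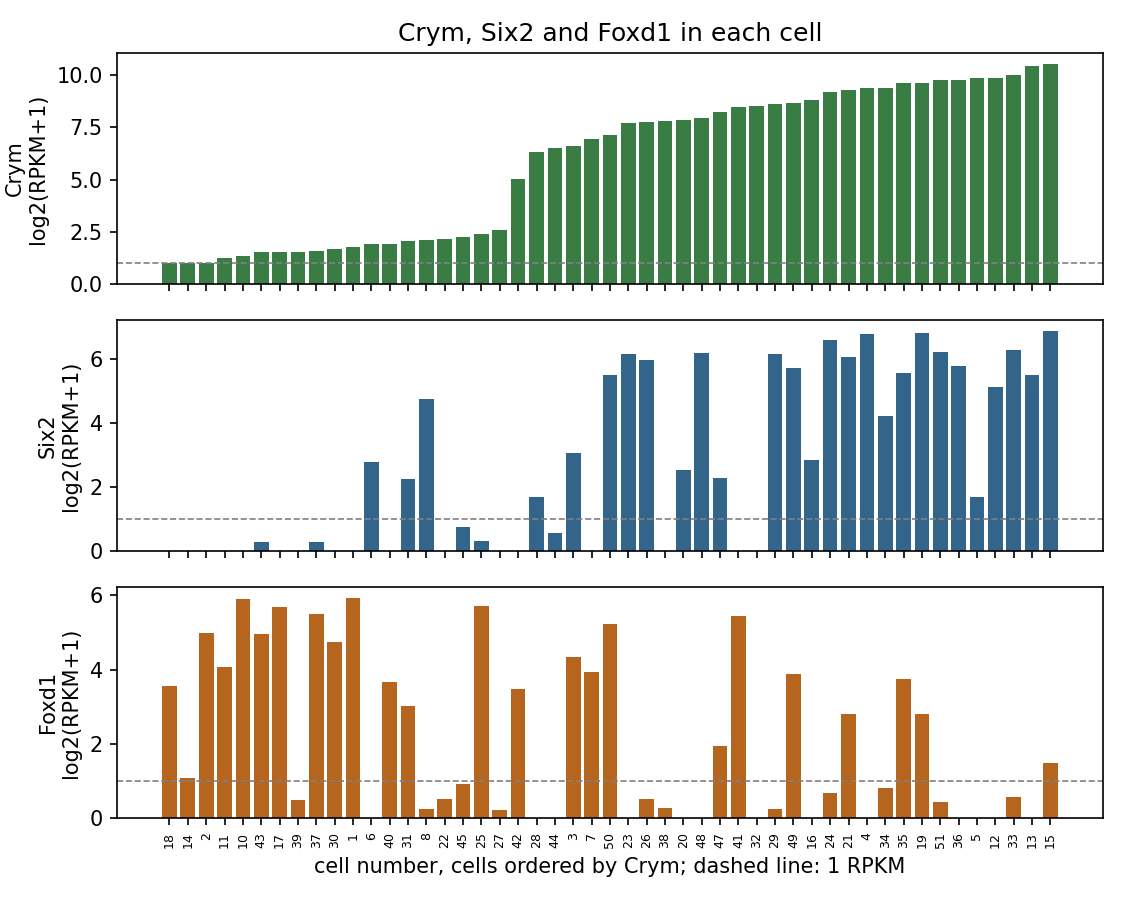
Crym, Six2 and Foxd1 as log2(RPKM+1) in each of the 49 cells, 1 bar per cell, with cells ordered by Crym and a dashed line at 1 RPKM. Crym steps from at most 4.92 RPKM in 19 cells to at least 31.4 RPKM in 30 cells; Six2 at 1 RPKM or more is found in 3 of the 19 cells and 24 of the 30 cells, and Foxd1 in 13 and 11.

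The nephron progenitor list of 16 genes was detected unevenly. Wt1 was at 1 RPKM or more in 47 cells and Sall1 in 44, both transcription factors required for early kidney development, with medians over all cells of 40.3 and 35.4 RPKM. Eya1 was found in 32 cells, the homeobox gene Meox1 in 30, the proteoglycan gene Spock2 in 25, the transcription factor gene Osr1 in 24 and the integrin gene Itga8 in 24. Gdnf, the ligand that draws out the ureteric bud, was found in 16 cells, with a highest value of 162 RPKM in cell 49. Cited1 and Uncx were each found in 12 cells, Tmem100 in 11, Pax2 in 8 and Fgf20 in 2. The 2 cells with Fgf20 were cell 25, which also held ureteric bud genes, and the shallow cell 7. Uncx never exceeded 8.83 RPKM, whereas Cited1 reached 281 RPKM in cell 36. All 12 cells with Cited1 also had Six2, where independent detection would give 6.61 cells. Six2 was shared with Eya1 in 26 cells (17.6 if independent), with Spock2 in 23 (13.8), with Osr1 in 21 (13.2) and with Gdnf in 12 (8.82).

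The stroma list was led by Meis1, a homeobox gene found in all 49 cells with a median of 108 RPKM, and by the chemokine gene Cxcl12, found in 40 cells with a median of 35.5 RPKM. Fat4 was found in 35 cells, the retinoic acid synthesis gene Aldh1a2 in 31, and the fibrillar collagen genes Col1a1 in 31, Col1a2 in 28 and Col3a1 in 28. The growth factor receptor genes Pdgfra and Pdgfrb were found in 26 and 19 cells, the retinoic acid receptor gene Rarb in 24, Sfrp1 in 21, Tbx18 in 18, Ecm1 in 15, Ntn1 in 8, Dcn in 6 and Lum in 3. Foxd1 (gene ID 15229; chromosome 13, 99124200 to 99126660) was found in 24 cells (49.0%, interval 34.4 to 63.7%), with a median of 15.0 RPKM in those cells and a highest value of 60.1 RPKM in cell 1. Foxd1 was shared with Col1a1 in 23 cells (15.2 if independent), with Col3a1 in 21 (13.7) and with Pdgfra in 21 (12.7). Tnc, the other list member, was not analysed here.

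**Figure D3:**
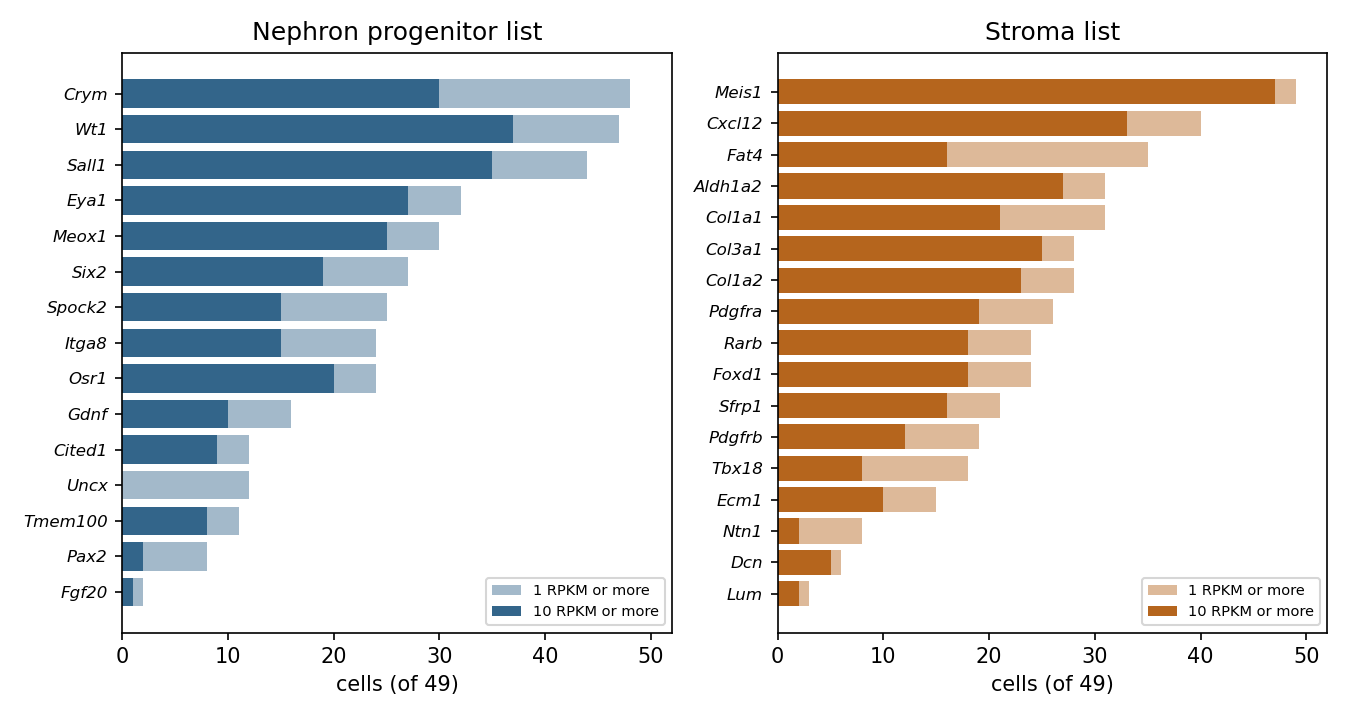
Number of the 49 cells in which 15 genes of the nephron progenitor list (left) and 17 genes of the stroma list (right) were at 1 RPKM or more (pale bars) and at 10 RPKM or more (dark bars). Crym goes from 48 to 30 cells between the thresholds and Six2 from 27 to 19, while Meis1 is at 1 RPKM or more in 49 cells and Foxd1 in 24.

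Whether individual mesenchymal cells hold transcripts of both nephron progenitor and stroma regulators was asked through Six2 and Foxd1. Both were at 1 RPKM or more in 9 of 49 cells (18.4%, exact 95% binomial interval 8.76 to 32.0%), fewer than the 13.2 cells that independent detection would give. Six2 without Foxd1 was found in 18 cells, Foxd1 without Six2 in 15, and neither in 7. Six2 was well above Foxd1 in 5 of the 9 cells, with 117 against 1.81 RPKM in cell 15, 112 against 5.96 in cell 19, 66.1 against 5.93 in cell 21, 46.1 against 12.4 in cell 35 and 52.1 against 13.8 in cell 49. The values were closer in cell 50, at 44.1 and 36.4 RPKM, and low for both genes in cell 47, at 3.86 and 2.83 RPKM. Foxd1 was the higher gene in cell 31, at 7.12 against 3.73 RPKM, and in the shallow cell 3, at 19.1 against 7.44 RPKM. The count rests on the threshold: it was 20 cells at 0.1 RPKM and 3 cells at 10 RPKM, below the 23.5 and 6.98 cells of independent detection in each case.

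At the level of the lists, 42 of 49 cells (85.7%, interval 72.8 to 94.1%) had 3 or more nephron progenitor genes together with 3 or more stroma genes at 1 RPKM or more. The median cell had 8 of the 16 nephron progenitor genes and 9 of the 17 stroma genes analysed. Over all 13093 genes analysed, the median detected per cell was 5210. Random lists were not run for the count of 42 cells. It is therefore not shown to exceed what the general rate of detection would give. The count rests in part on broadly detected members: without the 5 list genes found in 40 or more cells (Crym, Wt1, Sall1, Meis1 and Cxcl12), it was 17 cells (34.7%, interval 21.7 to 49.6%). In 16 of the 42 cells Crym took part only through its low range. With all list genes, the count was 27 cells at 5 RPKM and 24 cells at 10 RPKM. The same count of 3 or more genes was reached for the ureteric bud list in 2 cells and for the endothelial list in 1.

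Across the 49 cells, genes of the same list tended to be high in the same cells, and nephron progenitor genes tended to be low where stroma genes were high. The median Spearman correlation over pairs of nephron progenitor genes was 0.241 for the 14 genes found in 5 or more cells, above all 10000 random lists matched on mean expression, whose median was 0.0294. For the 16 stroma genes so found it was 0.386, again above all 10000 random lists, whose median was 0.0293. Over pairs of a nephron progenitor gene with a stroma gene, the median was -0.214, below all 10000 random pairs of matched lists, whose median was 0.0301. The random pairs were matched on mean expression but not on correlation within each list. They do not show how unusual the value is for lists whose own genes are correlated. Counts of shared cells, taken from the same cells and lists, gave the same picture. Among genes found in 5 to 44 cells, 63 of 66 nephron progenitor pairs and 102 of 105 stroma pairs, Foxd1 with Pdgfra among them, were shared by more cells than independent detection would give. Of the 180 cross pairs 144 were shared by fewer, such as Six2 with Pdgfra in 8 cells (14.3 if independent) and Six2 with Col3a1 in 11 (15.4). Percentiles among random lists describe these 49 cells and carry no p-value.

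Hox genes, which mark position along the body axis, were examined because the Hox11 paralogs Hoxa11, Hoxc11 and Hoxd11 set the metanephric level. At least 1 of the 3 was at 1 RPKM or more in 35 of 49 cells (71.4%, interval 56.7 to 83.4%). Hoxd11 was found in 27 cells, Hoxa11 in 20 and Hoxc11 in 8; 19 cells had 1 of them, 12 had 2 and 4 had all 3. Hox10 genes were more widespread, with Hoxa10 in all 49 cells, Hoxc10 in 47 and Hoxd10 in 37, and at least 1 Hox10 gene in every cell. Hoxc8 was found in 45 cells, Hoxa9 and Hoxb3 in 36 each, Hoxa5 and Hoxb6 in 35 each, Hoxd8 in 31 and Hoxc9 in 29. A median of 14 of the 32 Hox genes analysed was found per cell, from 9 to 22. Over all 13093 genes analysed, the median was 5210. Random sets of genes were not run here. Neither this count nor the share of cells with a Hox11 gene is therefore shown to exceed the general rate of detection. Hoxd11 was shared with Six2 in 19 cells (14.9 if independent) and with Foxd1 in 12 cells (13.2 if independent). The counts with Six2 lay nearer to independence at other thresholds: 22 cells (20.9) at 0.1 RPKM, 9 (8.53) at 5 and 5 (4.27) at 10. With Foxd1 they were 24 (23.5), 6 (8.14) and 2 (4.04). At 10 RPKM any Hox11 gene was found in 21 cells.

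**Figure D4:**
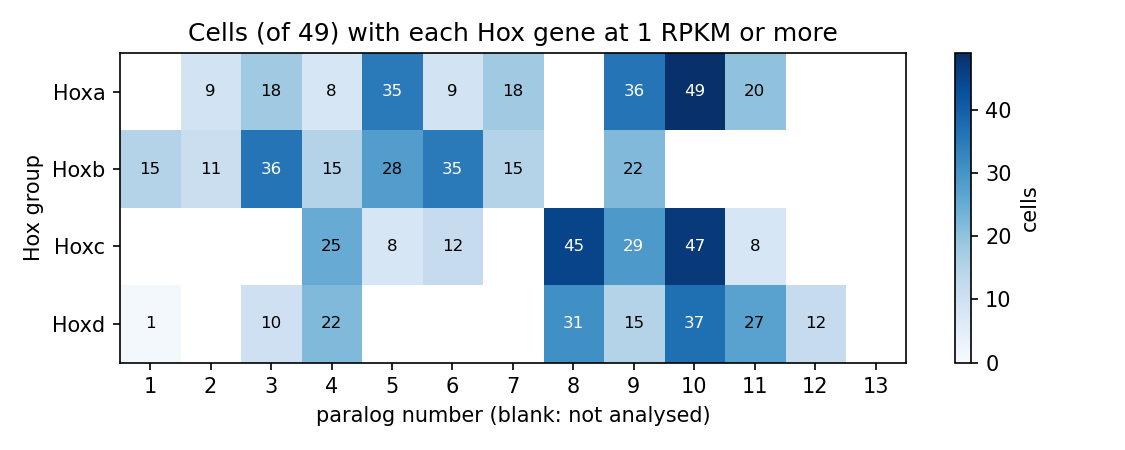
Number of the 49 cells with each of 32 Hox genes at 1 RPKM or more, by Hox group (rows) and paralog number (columns); blank squares were not analysed. Counts are highest at Hoxa10 with 49 cells, Hoxc10 with 47 and Hoxc8 with 45, and lower for Hoxd11 with 27, Hoxa11 with 20 and Hoxc11 with 8.

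At least 1 ureteric bud gene was at 1 RPKM or more in 16 cells and at least 1 endothelial gene in 9, and most genes of each list were found together in 1 cell. In cell 25, 10 of the 11 ureteric bud genes analysed were at 1 RPKM or more. They included Calb1 at 473 RPKM, Krt8 at 88.0, the Gdnf receptor gene Ret at 59.6, Epcam at 39.9 and Wnt9b at 24.4. Cell 25 also had 12 of the 17 stroma genes at 1 RPKM or more, Foxd1 at 51.7 RPKM among them, and Crym at 4.19 RPKM. It detected 6330 genes, against a median of 5210. Whether 1 cell or 2 cells in the chamber gave these values cannot be told from them. In cell 27, all 9 endothelial genes analysed were detected, with Egfl7 at 337 RPKM, Esam at 233, Cldn5 at 206, Kdr at 130 and Cdh5 at 73.4, beside Laptm5 at 46.2 and Fcer1g at 41.1 RPKM from the macrophage list. No other cell had more than 3 ureteric bud genes or more than 1 endothelial gene. Gata3 was the most widely found ureteric bud gene, in 10 cells, and was highest in the shallow cell 7, at 146 RPKM, and cell 12 had Krt18 at 33.3, Krt8 at 10.6 and Krt19 at 7.92 RPKM. Of the macrophage list only 3 of 11 genes were analysed, and no cell had all 3 (0 of 49 cells, which allows a share of up to 6.12%); cell 27 had 2. Of the 3 muscle genes analysed, Des was found in 31 cells and no cell had all 3. Alas2, the only erythroid gene analysed, was found in 7 cells, so that no count of 3 genes was possible for that list. From the neural list, Elavl4 was found in 23 cells, Stmn2 in 5 and Tubb3 in 4, and 1 cell, the shallow cell 7, had 3 of these genes.

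Genes of later nephron segments were rare, apart from 2 members. Cdkn1c, a cell cycle inhibitor gene of the podocyte list, was found in all 49 cells with a mean of 389 RPKM. Ccnd1, a cyclin gene of the early nephron list, was found in 31 cells. Other members were found in few cells: Kirrel in 15, Jag1 in 10, Pax8 in 7, Lef1 in 4, Wnt4 in 3 and Lhx1 in 1. Early nephron genes reached 3 in 7 cells and podocyte genes in 5. The highest Wnt4 value was 52.2 RPKM in cell 28. From the proximal tubule list Slc5a2 and Aqp1 were found in 1 cell only, cell 30. From the list of later tubule segments Pou3f3 and Sim1 were found only in cell 25, which had 10 ureteric bud genes. That cell was also the 1 with Lhx1. All of these tubule genes stood at 8.67 RPKM or less, and the other members of these 2 lists were not analysed here.

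Cell cycle genes differed widely between cells. All 41 genes of the G1/S list and 45 of the G2/M list were analysed, and a cell had from 12 to 39 of the former and from 5 to 45 of the latter at 1 RPKM or more. Nasp, Tyms and Mcm4 were found in 49, 48 and 48 cells, and Hmgb2, Tmpo and Cks1b in 49, 48 and 46. The median Spearman correlation within the G2/M list was 0.556, the highest of the lists examined, and 0.233 within the G1/S list, both above all 10000 random lists. Among the 15 genes with the most variation for their mean level, Ccnb1, Ube2c, Aurka and Aurkb act in mitosis. Crabp1, a retinoic acid binding protein gene, had an SD of log2(RPKM+1) of 4.00, as did Ccnb1, and was found in 29 cells at up to 875 RPKM and listed at 0 in 19. The remaining 10 were Asb4 in 25 cells, Rgs5 in 24, Snora31 in 17, Cldn9 in 16, Tmem37, Sncg and Myl9 in 15 each, Efemp1 in 14, Snord87 in 13 and Snord73a in 10. Snora31, Snord87 and Snord73a are short genes, so a single read weighs more in their RPKM. Snora31 (76247730 to 76247841) lies within Tpt1 (76245063 to 76248110) on chromosome 14. Snord73a (85942713 to 85942780) lies within Rps3a (85941862 to 85946590) on chromosome 3. Reads of Tpt1 and Rps3a may therefore be counted in them. The highest value of Ccnb1, 8013 RPKM, was in the shallow cell 3.

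Clustering on 500 variable genes gave 5 clusters of 18, 8, 6, 4 and 13 cells, at a mean silhouette of 0.244, close to the 0.228 of 2 clusters and not far above the 0.175 of data with each gene shuffled over cells. Cluster 1 was defined by Ccnb1, Ube2c, Aurkb, Aurka and Tpx2, with 6 cell cycle list genes among its top 10. Cluster 2 was defined by Asb4, Crabp1, Pdgfra, Ebf1 and Anxa5, cluster 3 by Aldh9a1, Acp6 and Ints3, cluster 4, which held the shallow cells 3 and 7 beside cells 42 and 45, by L3mbtl3, Lpar6 and Tfe3, and cluster 5 by Timm10, Tsta3, Shmt1, Meox2 and Crym. None had 3 fixed cell type markers among its top 10 genes, so the clusters were left unnamed. The number of clusters was 3 without the cell cycle list genes and 3 without cells 3 and 7, and 2 after removal of the trend with genes detected.

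Of 28 genes for signals that act between mesenchyme, stroma and ureteric bud, 27 were analysed, and a median of 10 was found per cell. Over all 13093 genes analysed, the median was 5210. The members found in most cells were the sprouty gene Spry2 in 46 cells, the Slit receptor gene Robo2 in 45, the fibroblast growth factor receptor gene Fgfr1 in 44 and the BMP receptor gene Bmpr1a in 40. Other receptor and feedback genes were found in fewer, with Fgfr2 in 32 cells, the Gdnf receptor gene Gfra1 in 24 and Spry1 in 12. Among ligand genes, Fgf10 was found in 25, Slit2 in 21, Bmp7, Rspo3 and Vegfa in 18 each, Gdnf in 16, Rspo1 and Wnt5a in 15 each, Bmp4 in 10 and Fgf9 in 8. The median correlation within this list, 0.0302, lay at the 52.7th percentile of random lists, unlike that of the nephron progenitor and stroma lists.

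Immediate early genes of dissociation stress were found in part of the cells, with Ier2 in 33, Jun in 29, Dusp1 in 20 and Fos in 19; 28 cells had 3 or more of the 8 genes analysed. Their median correlation was 0.159, at the 99.6th percentile of random lists, and that of the 10 housekeeping genes, with Eef1a1 and Actb in all cells, was 0.102, at the 89.1st percentile. Y-linked genes were found in every cell although the labels give the sex as both: Ddx3y and Eif2s3y were each found in 44 cells, Uty in 42 and Kdm5d in 24. The summed level of these 4 genes ranged from 8.63 RPKM in cell 27 to 511 RPKM in cell 44, and their median correlation, 0.0663, lay at the 68.0th percentile of random lists. Xist was not analysed here, so no count of cells with both Xist and a Y-linked gene is given.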

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

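Leaving out cells 3 and 7, cells 25 and 27, or the list genes found in 40 or more cells was chosen after the data were seen; the other alternatives were set before. Of 65 values computed for 11 results, 40 stayed within a limit and 25 moved beyond it. The limit was the 95% interval of the share, 1.5 times the count or 1 SD of the random lists. The correlations kept their sign in every setting, and counts cannot change sign. At 0.1 RPKM the count of cells with Crym was 49, with Six2 and Foxd1 20, and with 3 or more genes of both lists 49. At 5 RPKM it was 30 for Crym and 27 for both lists. At 10 RPKM the median of genes detected was 3437, and the counts were 30 for Crym, 19 for Six2, 18 for Crym with Six2, 3 for Six2 with Foxd1, 24 for both lists and 21 for any Hox11 gene. Each such move follows from the threshold itself. Without the list genes found in 40 or more cells, the count of cells with 3 or more genes of both lists was 17. Of the genes left out, Crym, Wt1 and Sall1 were found in 48, 47 and 44 cells. These alone made up 3 nephron progenitor genes in most cells. The median correlation within the nephron progenitor list was 0.274 with Pearson on log2(RPKM+1), 0.276 with log2(RPKM+0.1) and 0.216 without the trend with genes detected. Within the stroma list it was 0.335 with Pearson on log2(RPKM+1) and 0.455 for genes detected in 10 or more cells. Between the lists it was -0.262 without the trend and -0.236 for genes detected in 10 or more cells. In every setting run the within-list values stayed above, and the between-list value below, all 10000 random draws. The random pairs of lists were not matched on correlation within each list in any setting. The number of clusters was 2 with 200 variable genes, 2 with 10 components, 2 without the trend, 3 without the cell cycle lists and 3 without cells 3 and 7, and otherwise 4 to 6; the cause was not tested. Leaving out cells with fewer than 0.5 times the median number of genes removed 0 cells and so tests nothing; it is not among the 65 values. The count of cells with Xist and a Y-linked gene was not run. No paired analysis was possible because the cells form 1 group. Depth limits the low values of cells 3 and 7 most, at 0.0346 and 0.0462 times the reads of the median cell.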

Other observations

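Abca14, the gene next to Crym in the table, starts 1976 bases beyond the end of Crym on chromosome 7 and was at 1 RPKM or more in 18 cells. All 18 were among the 30 cells in the high range of Crym, and none among the 19 cells in the low range; the highest Abca14 value, 76.7 RPKM, was in cell 32, where Crym stood at 362 RPKM. Abca14 was singled out after its values were seen, and the table does not tell transcripts of the gene itself from transcripts that run on from a neighbour or from the transgene.

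Some list members stood high in single cells. Dcn and Lum, proteoglycan genes of the stroma list, stood at 325 and 102 RPKM in cell 39, which had 12 of the 17 stroma genes analysed at 1 RPKM or more, and were found in 6 and 3 cells in all. Epcam stood at 163 RPKM in cell 29, Cd68 at 123 RPKM in cell 13 and Tubb3 at 278 RPKM in cell 17, each with no other analysed gene of its list (ureteric bud, macrophage and neural) at 1 RPKM or more in that cell. Dll1, a Notch ligand gene, was found in 1 cell, cell 27, at 39.9 RPKM beside the endothelial genes. Rspo3 and Gfra1 were highest in cell 13, at 299.7 and 358 RPKM, where 10 signalling genes were found. Each was singled out after its values were seen.

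All tests below were chosen after the results were seen. Crym was above 0 in every cell, with 19 cells at 0.999 to 4.92 RPKM, including cell 27 with its endothelial genes. Reads carried evenly from the pooled libraries of the lane would leave a like trace, in percent of the mean, of other abundant genes. Of 7 other genes that were at least 0.5 times as abundant as Crym and low in 10 or more of the 47 deeper cells, Crabp1 was listed at 0 in 18 deeper cells, Ube2c in 5, Ccnb1 in 4, Tubb4b in 3 and Kpna2 and Rrm2 in 1 each, while Enc1, like Crym, was at 0 in none. The low end (10th percentile) was 0.531% of the mean for Crym and from 0 for Crabp1 to 0.316% for Rrm2 for the others. In 6 of the 19 cells 2 or more of the 7 genes lay more than 3 times below the trace that Crym would need. In 8 cells 1 gene did and in 5 none. The rule for this comparison asked for 2 or more such genes in most of the cells. Loss of single reads by sampling was not modelled. Genes whose trace would reach 3 RPKM, at the reads of the median cell, were also examined. At most 0.977% of them were listed at 0 in any of the 19 cells. This second comparison could not exclude a trace. For so small a trace only 53 to 512 abundant genes per cell qualified, and 557 genes were detected in every cell. Such genes could be above 0 with or without a trace. The first comparison fell short of its rule and does not decide, so an even trace stays open. Reads carried from single libraries were not tested. Reads from genomic DNA over the locus would also be expected over Abca14, which starts 1976 bases beyond Crym. But Abca14 was listed at 0 in 22 of the 49 cells and reached 1 RPKM in no cell of the low range. Tmem159, on the other side, was listed at 0 in 24 cells. It ends at 127264500, far from the start of Crym at 127329898, so it does not test reads confined to the locus. Low transcription of Crym in these cells, or transcripts of the transgene, may account for the low range and stay open, as neither was tested.

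Six2 and Foxd1 were found together in 9 cells. The tables argue against an even trace of the lane. It could not reach the mean of a gene, whereas the lower of Six2 and Foxd1 stood above its mean in 3 of the cells. In each of the 9 cells a trace large enough for the lower of the pair would also leave other genes above 0, but from 3.29% of the genes whose trace would reach 3 RPKM (7 of 213, in the shallow cell 3) to 28.2% were listed at 0. Reads carried from single libraries were not tested. A chamber with 2 cells should detect more genes, and 7 of the 9 cells detected more than the median cell, with up to 6510 in cell 47, while cell 15 (4924) and the shallow cell 3 (4954) did not. Cells that detect more genes also detect any pair more often, so 2 cells in a chamber and joint expression in 1 cell cannot be told apart from these values. No biological explanation was tested, since the design has 1 group.

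Y-linked transcripts were found in all 49 cells although the labels give the sex as both. The tables argue against an even trace of the lane here too. The summed level of the 4 Y-linked genes stood above its mean in 18 cells. Some cells must lie above any mean, so this says nothing of the cells below it. The argument rests on genes listed at 0. In the 49 cells, from 9.75% (468 of 4798, in cell 25) to 48.3% of the genes whose trace would reach 3 RPKM were listed at 0. In cell 27, where the summed level was lowest, at 6.15% of its mean, it was 210 of 2036 genes. Xist was not among the genes analysed. By the rule of the table it may have stayed at 3 RPKM or less in every cell. The annotation is not given, so it may also have had no entry. Embryos of 1 sex, and chambers with a male and a female cell, were therefore not tested, and the sex of the embryos is left open.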
